A study of Nicotiana benthamiana
Tenuivirus oryzaclavatae and Nicotiana benthamiana with 13 samples.

How the data were processed

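The series holds 13 libraries from leaves of wild-type Nicotiana benthamiana at 7 days of infection: 6 mRNA libraries (3 RSV-inoculated and 3 mock-inoculated), 6 small RNA libraries (3 and 3) and 1 degradome library, which the labels describe as a pool made from the replicates of the RSV group. Groups and replicate numbers were taken from the labels. The series' design text calls the replicates biological. The plants were inoculated by rubbing with an extract of RSV-infected rice leaves or mock-inoculated, per the labels. The mRNA kit keeps strand, per the labels' protocols, and how strand was used in counting is not given in the sources used here. Degradome libraries capture the 5′ ends of uncapped, polyadenylated RNA, so a cleavage site appears as a pile of tags with the same start.

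The mRNA table gives estimated counts for 60028 transcript models, deposited by the authors, with a Niben044 model name and, for 34918 models, a second Niben101 name. Of its count cells, 62.6% are not whole numbers, so reads that fit several models were shared between them before deposit. The table also holds RPKM values made by the authors, which were not used here. It holds the authors' own adjusted p-value, called FDR and rounded to 2 decimals per the file headers, and the authors' log2 fold change, which entered no test here. The submitters' processing notes name Bowtie and DESeq 1.4 without saying what each did, and the aligner settings, the counting program and the genome build are not given in the sources used here. Descriptions, absent for 15326 models, were used to group transcripts. The GO texts in the same table were not used, because few of them fitted the descriptions beside them. Among models with GO text, a fitting one stood at 7.43% of kinases and at 7.60% of all other models. The shares were 3.60% against 2.52% for ribosomal proteins and 1.72% against 1.29% for cytochrome P450. No reference genome was used here, so positions are given within transcript models.

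The small RNA table gives RSV-derived sequences of 19 to 24 nt, with their viral segment and a value per library that the header calls TPM. The values deposited by the authors were RPM, reads scaled to the total of the library, with no length term: in each column 100% of the values lay within 0.01 of a whole multiple of the smallest one. That step gave the total of each library, and whole reads were recovered from it. Implied totals were 12313987, 12100125 and 10431719 reads in mock replicates 1 to 3 and 9198647, 7322555 and 8896643 reads in RSV replicates 1 to 3. The smallest value of mock replicate 1 rests on only 44 sequences above 0, so its total is less certain. The table has 76990 lines for 72416 distinct sequences, since 4494 pairs of segment and sequence stand in 2 lines. It gives neither the strand of a sequence nor the length of a segment, so the strand share and the values per kilobase were not made.

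The degradome table gives, per position of a transcript, the number of tags starting there, a number weighted by mapping places, the tags with 1 place and a category score from 0 to 4 assigned by the authors, where 0 marks a position that alone holds the most tags of its transcript. The mapped read size was 33 nt per the file headers. Tags were placed at every location they fitted: 8091759 placements lay in 49288 transcripts, and 1143724 tags had 1 place.

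For the mRNA comparison the estimated counts were rounded to whole numbers and filtered with filterByExpr, which left 30537 transcripts. They were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, RSV against mock, two-sided) in R 4.3.3, and transcripts with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values were scaled with the TMM factors. Library totals were 4511063, 5333198 and 4398853 estimated counts in mock replicates 1 to 3 and 4372959, 4814222 and 6598662 in RSV replicates 1 to 3. The biological coefficient of variation was 0.166. A fold against mock libraries that were all at 0 was computed against a floor of 3 counts over the 3 mock libraries together (0.246 CPM) and is a lower bound. Where the mock libraries held 1 to 3 counts in all, the ratio of counts is given with its 95% exact interval. All such intervals and floors cover counting error only.

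Lists of genes were fixed as phrases searched in the description text. They were RNA silencing machinery, Light harvesting and photosystems, Calvin cycle, Chlorophyll synthesis, Pathogenesis-related proteins, Salicylic acid signalling, Disease resistance proteins, Jasmonate, Ethylene, Auxin, Gibberellin, Cytokinin, Abscisic acid, Brassinosteroid, WRKY factors, NAC factors, Heat shock proteins and chaperones, ER folding and stress, Proteasome, Cytosolic ribosomal proteins, Chloroplast ribosomal proteins, Histones and DNA replication, Cyclins and cell division, Cell wall, Phenylpropanoid and lignin, Sesquiterpenoid phytoalexins, Glutathione transferases, Peroxidases and oxidases, Autophagy, Ubiquitin E3 ligases, Receptor-like kinases, Conserved miRNA target families, Plasmodesmata and callose, senescence markers, Root nicotine synthesis, Trichome, Pollen and flower, and Organelle-encoded proteins, the last 4 as markers of other tissues or cell types and of RNA quality. Of the 38 lists, 36 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 36. The files write "beta-1 3-glucanase" without a comma, so these enzymes were missed by the phrase for pathogenesis-related proteins and are given as a group of their own.

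Named transcripts followed a fixed rule: the 10 largest rises and 10 largest falls among called, described transcripts whose 3 RSV libraries all lay on one side of the 3 mock libraries, with a mean of at least 5 CPM, and up to 2 risen and 2 fallen members of each called list, and of the silencing and pathogenesis-related lists, with a mean of at least 1 CPM. For small RNA the rule took the 5 sequences with the highest mean in the RSV libraries. For the degradome it took the 5 described transcripts with the most tags at a category 0 position and the 5 such members of the miRNA target families. These rules, the lists, the tests and the first set of alternatives were fixed before the data were examined.

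RSV-derived small RNA totals were compared on log2(RPM + 1) with an exact two-sided permutation test. Single sequences with a mean of at least 10 RPM in one group were tested with limma 3.58.1 on log2(RPM + 1), a scale that understates the change of rare sequences, and the recovered whole reads were tested with edgeR and DESeq2 1.42.0 as added alternatives. A degradome peak was a category 0 position with at least 10 tags. Peaks were compared between groups of transcripts with Fisher's exact test and with 10000 random lists matched in 20 bins of total tags, using Python 3.11.15 with scipy 1.17.1. With 1 degradome library and no mock counterpart, these comparisons describe that library only.

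Alternatives covered normalization, filters, thresholds, DESeq2, the replicate number as a block, other gene set tests, pseudocounts, tag minimums, and leaving out each library in turn. Scaling by library totals alone, moving part of the recovered small RNA reads by a column, counting only tags with 1 mapping place and the count tests on recovered reads were added after seeing the data. The tests were checked on simulated data made from the mRNA libraries' means: edgeR recovered 56% of 2-fold and 95% of 4-fold changes among 30537 transcripts, and 7.17% of its calls were unchanged transcripts. The simulation changed far fewer transcripts than were called in the real data. The adjusted threshold depends on that number, so these shares need not hold for the real comparison. Camera called the changed list and 0 of 35 others. The transcripts were simulated independently of each other, so this does not show how often camera calls lists whose members vary together. For the 517 small RNA sequences limma recovered 1% of 2-fold and 82% of 16-fold changes, and 3.49% of its calls were unchanged sequences.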

Results

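Leaves of Nicotiana benthamiana, a wild relative of tobacco that is widely used as a host in plant virology, were profiled at 7 days of infection with rice stripe virus (RSV), a segmented RNA virus of cereals, and compared with leaves of mock-inoculated plants. The mRNA of 3 RSV and 3 mock replicates was sequenced, as were the small RNAs of 3 RSV and 3 mock replicates, and 1 degradome library was made from a pool of the RSV replicates. Library totals lay between 4372959 and 6598662 estimated counts for mRNA. They lay between 7322555 and 12313987 reads for small RNA, of which the deposited table lists the RSV-derived ones. The degradome held 8091759 tag placements in 49288 transcripts.

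The mRNA comparison asks how host transcripts responded to RSV infection. The leaf transcriptome differed widely between RSV and mock leaves: of 30537 transcripts tested, 5470 rose and 5521 fell (10991 called by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05). By at least 2-fold, 2721 rose and 2598 fell (5319). More members of the photosynthesis, cell division, histone and cell wall lists fell than rose, and more members of the WRKY, NAC, proteasome, autophagy and RNA silencing lists rose than fell. Of 36 tested lists 18 were called by camera with its default correlation between transcripts, and none with an estimated correlation, where the adjusted p of the 18 was 0.281 to 0.773. The 3 RSV libraries did not overlap the 3 mock libraries for 15418 transcripts (50.5%), where chance gives 10%. The correlation of log2 CPM across transcripts was 0.954 to 0.980 between RSV libraries, 0.956 to 0.967 between mock libraries and 0.793 to 0.903 between the groups. RSV replicate 3 stood farthest from the mock libraries on the first principal component (73.9% of the variance), at 101.3 against 58.9 and 52.3 for RSV replicates 1 and 2. Without it 9246 transcripts were called, 4338 of them by at least 2-fold. In the authors' deposited table an FDR under 0.05 was given for 6069 transcripts, of which 5817 were tested here and 5812 called.

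The split between rises and falls depended on the scaling. Scaled by library totals alone, 12561 transcripts rose and 2715 fell, and 5900 rose and 1029 fell by at least 2-fold. The median log2 change of all tested transcripts was then 0.43 against 0.01 with TMM factors. The changes below are relative to the TMM centre. Counts were shared between models before deposit, so the values of near-identical copies, which are common in this allotetraploid, are uncertain one by one.

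Most transcripts for light capture and photosynthetic electron transport fell: 167 of the 198 measured members of the Light harvesting and photosystems list fell and 5 rose (171 and 5 adjusted over the list alone, 145 and 7 when scaled by library totals). Their summed level was 106330 ± 17999 CPM in RSV leaves against 216170 ± 4763 CPM in mock leaves (mean ± SD, n = 3 each). All 76 transcripts described as chlorophyll a-b binding proteins, the antenna proteins of the photosystems, fell, from a sum of 154510 ± 3704 to 73415 ± 14073 CPM, and 69 of them also fell when scaled by library totals. This group and the other groups called added in these paragraphs were chosen after the values were seen. Chloroplast photosystem II-associated protein (NbS00020769g0006.1) was 4.03-fold lower, at 165 ± 72.9 against 662 ± 99.1 CPM. Against the trend of the list, Ferredoxin--NADP reductase (NbS00018068g0003.1), which passes electrons to NADP, was 2.66-fold higher at 57.7 ± 7.75 against 21.7 ± 3.00 CPM. Blue copper protein (NbS00023093g0022.1) was 2.92-fold higher and Blue copper-like protein (NbS00005232g0008.1) 4.86-fold lower (7.35-fold without RSV replicate 2). Both entered the list through a plastocyanin-like domain and are not plastocyanin, the photosynthetic electron carrier. The list median was -1.05 on the log2 scale (camera, adjusted p = 1.97e-31, and adjusted p = 0.345 with an estimated correlation).

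Carbon fixation and chlorophyll synthesis followed the same direction. In the Calvin cycle list 50 of 74 members fell and 8 rose (52 and 8 adjusted over the list alone), and the summed level was 38609 ± 5716 CPM in RSV and 101970 ± 2088 CPM in mock leaves. Scaled by library totals 40 fell and 13 rose, with a median of -0.48. Ribulose-1 5-bisphosphate carboxylase/oxygenase activase 1 (NbS00028170g0001.1), which keeps Rubisco active, was 4.65-fold lower (332 ± 60.2 against 1544 ± 170.3 CPM). Fructose-1 6-bisphosphatase class 1 (NbS00020569g0013.1), which acts in the regeneration of the CO2 acceptor and in sucrose synthesis, was 4.36-fold lower (159 ± 63.3 against 691 ± 27.4 CPM). The Rubisco small chain, an added group, fell in 10 of 11 transcripts. The risen members named by the rule were 1-deoxy-D-xylulose-5-phosphate synthase (NbS00008499g0018.1, 3.36-fold, not called by DESeq2 with adjusted p = 0.0563) and Pyruvate dehydrogenase E1 component subunit beta (NbS00019709g0016.1, 2.48-fold). These enzymes of isoprenoid precursor and acetyl-CoA synthesis share a transketolase domain with the cycle's own enzyme. In the Chlorophyll synthesis list 43 of 48 members fell and 2 rose (43 and 2 adjusted over the list alone, 35 and 3 when scaled by library totals). Coproporphyrinogen III oxidase (NbS00016768g0011.1) was 4.08-fold lower, and Protochlorophyllide reductase (NbS00014869g0016.1), which makes chlorophyllide in the light, was 3.78-fold lower (136 ± 89.8 against 514 ± 46.1 CPM). A copy of Glutamyl-tRNA reductase (NbS00025001g0017.1), at the head of the pathway, was 3.53-fold higher at 3.81 ± 0.721 against 1.06 ± 0.0321 CPM. List medians were -0.90 for the Calvin cycle (camera, adjusted p = 3.79e-16, and adjusted p = 0.307 with an estimated correlation) and -1.18 for chlorophyll synthesis (camera, adjusted p = 9.46e-15, and adjusted p = 0.345 with an estimated correlation).

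**Figure D1:**
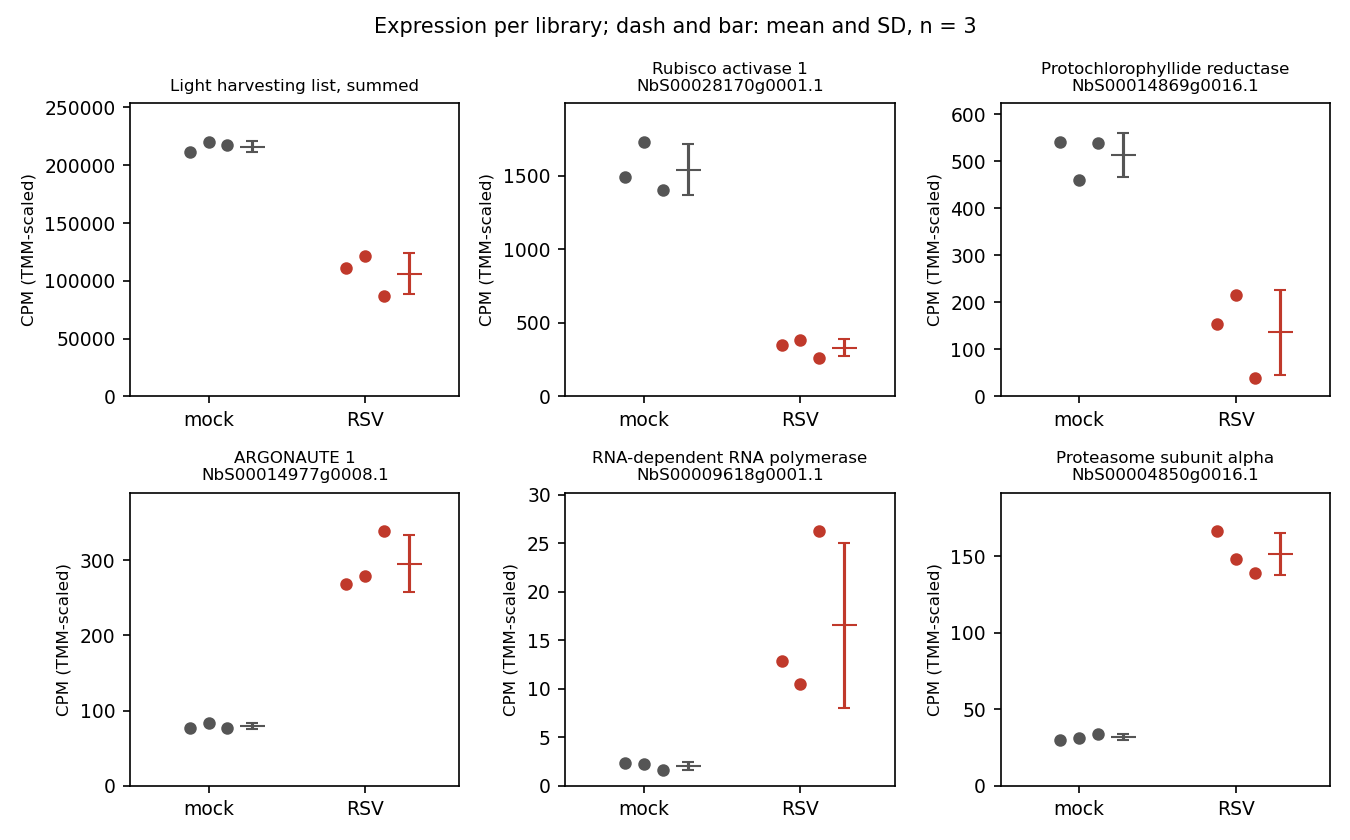
Level per library in CPM scaled with TMM factors (vertical axes, each from 0) for the summed light harvesting list and 5 transcripts, with mock libraries in grey and RSV libraries in red; the dash and bar give the mean and SD of 3 libraries. In every panel the 3 RSV libraries lie on one side of the 3 mock libraries: below them for the light harvesting sum, Rubisco activase and protochlorophyllide reductase, and above them for ARGONAUTE 1, the RNA-dependent RNA polymerase and the proteasome subunit. For the 5 transcripts this was a condition of being named.

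Plastid gene expression transcripts were mixed. The Organelle-encoded proteins list fell in 17 of 35 members and rose in 3 (19 and 3 adjusted over the list alone, 12 and 3 when scaled by library totals), with a summed level of 807 ± 154 CPM in RSV and 1701 ± 224.0 CPM in mock leaves. Most of its members are described as Ycf proteins of types encoded in the plant nucleus, so it does not measure organelle RNA. Its named members, Ribosomal protein PSRP-3/Ycf65 (NbS00046595g0013.1, 2.81-fold lower) and the Ycf48-like photosystem II assembly factor (NbS00049766g0015.1, 2.08-fold lower), are of this kind. In the Chloroplast ribosomal proteins list 79 of 300 members fell and 28 rose (79 and 28 adjusted over the list alone). Its summed level was 10823 ± 1946 CPM in RSV and 17299 ± 2364 CPM in mock leaves. 50S ribosomal protein L12-C (NbS00026544g0001.1) was 4.81-fold lower (19.8 ± 7.22 against 94.2 ± 17.9 CPM) and 50S ribosomal protein L18 (NbS00014933g0005.1) 4.36-fold lower. A transcript described as 30S ribosomal protein S19 (NbS00000565g0004.1) was 27.3-fold higher (57.0 ± 13.6 against 2.10 ± 0.761 CPM) and 30S ribosomal protein S1 (NbS00030241g0011.1) 2.59-fold higher. The domain text of that S19 transcript names a eukaryotic and archaeal ribosomal protein. The organelle list had a median of -0.76 (camera, adjusted p = 8.02e-05, and adjusted p = 0.382 with an estimated correlation). The chloroplast ribosomal list had a median of -0.06 (camera, adjusted p = 0.0279, and adjusted p = 0.773 with an estimated correlation), and turned to 0.35 when scaled by library totals, where 116 rose and 70 fell. It was not called without mock replicate 3 (adjusted p = 0.255, median 0.09), without RSV replicate 3 (adjusted p = 0.17, median 0.06) or by fry (adjusted p = 0.32). Over its 12 alternatives the adjusted p ran from 0.000748 to 0.773.

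RNA silencing transcripts, the host machinery that cuts viral RNA into small RNAs and uses them against it, rose on balance: 19 of 44 members of the RNA silencing machinery list rose and 7 fell (21 and 7 adjusted over the list alone, 30 and 2 when scaled by library totals). ARGONAUTE 1 (NbS00014977g0008.1), which loads small RNAs and slices matching RNA, was 3.74-fold higher at 295 ± 38.2 against 78.9 ± 3.86 CPM (adjusted p = 9.838e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). An RNA-dependent RNA polymerase (NbS00009618g0001.1), of the family that makes double-stranded RNA for amplifying silencing, was 8.16-fold higher at 16.5 ± 8.52 against 2.04 ± 0.379 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.001097). Among added groups, 10 Argonautes rose and 5 fell of 18 (13 and 2 when scaled by library totals), 5 of 6 RNA-dependent RNA polymerases rose, and none of 4 Dicer transcripts was called, at a summed 86.8 ± 3.09 against 82.9 ± 7.61 CPM. Another ARGONAUTE 1 copy (NbS00050901g0017.1, 1.56 ± 0.684 against 4.03 ± 2.24 CPM) and Argonaute 4-like protein (NbS00018144g0003.1, 88.5 ± 20.7 against 131 ± 14.1 CPM), which acts in RNA-directed DNA methylation, were 2.80-fold and 1.49-fold lower. Both lost their call when scaled by library totals and without some libraries: the first without mock replicate 2, mock replicate 3 or RSV replicate 3, the second without any library except RSV replicate 2 and without the low-count filter. The list median was 0.52 (camera, adjusted p = 0.00259, and adjusted p = 0.307 with an estimated correlation).

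More WRKY and NAC transcription factors, of plant families that act in defence, stress and senescence, rose than fell. Of 62 WRKY factors 37 rose and none fell (41 rose and 1 fell adjusted over the list alone, 52 and 0 when scaled by library totals), and their summed level was 1143 ± 337 against 444 ± 67.2 CPM. WRKY transcription factor 6 (NbS00025409g0005.1) was 47.2-fold higher (23.3-fold without RSV replicate 3 and 84.5-fold without mock replicate 2), and a WRKY transcription factor (NbS00025517g0003.1) was 25.3-fold higher at 58.2 ± 30.7 against 2.27 ± 0.854 CPM. Of 56 NAC factors 31 rose and 4 fell (33 and 8 adjusted over the list alone, 40 and 1 when scaled by library totals). A NAC domain class transcription factor (NbS00032439g0005.1) was 86.0-fold higher at 30.2 ± 2.57 against 0.305 ± 0.331 CPM (194-fold without mock replicate 2). A NAC domain transcription factor (NbS00026127g0018.1), at 0 in all mock libraries, was at least 31.5-fold higher (at least 11.2-fold without RSV replicate 3), and a NAC domain protein (NbS00009363g0012.1) was 1.98-fold lower. Medians were 1.06 for WRKY factors (camera, adjusted p = 1.24e-13, and adjusted p = 0.307 with an estimated correlation) and 0.76 for NAC factors (camera, adjusted p = 2.72e-13, and adjusted p = 0.307 with an estimated correlation).

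More ethylene and disease resistance transcripts rose than fell. In the Ethylene list 63 of 181 members rose and 23 fell (70 and 27 adjusted over the list alone, 92 and 10 when scaled by library totals). A 1-aminocyclopropane-1-carboxylate oxidase (NbS00008811g0004.1), which makes ethylene in the last step of its synthesis, was at 17.3 ± 10.2 CPM in RSV leaves, with 1 count in the mock libraries together, a ratio of 231 (95% exact interval 41.1 to 9129; 141 without RSV replicate 3, and at least 44.1-fold higher without mock replicate 2). Of 45 transcripts described as oxidases or synthases of 1-aminocyclopropane-1-carboxylate, an added group, 11 rose and 7 fell (22 and 3 when scaled by library totals). Their summed level was 2211 ± 214 CPM in RSV and 2276 ± 319 CPM in mock leaves. Ethylene-responsive transcription factor 2 (NbS00025008g0007.1), at 0 in all mock libraries, was at least 21.3-fold higher (at least 11.9-fold without RSV replicate 3). Ethylene-responsive transcription factor 4 (NbS00027293g0001.1) was 3.09-fold lower and factor 1b (NbS00027758g0001.1) 3.05-fold lower. The Disease resistance proteins, mostly NBS-LRR receptors that recognise pathogens, rose in 31 of 105 members and fell in 6 (31 and 6 adjusted over the list alone, 50 and 1 when scaled by library totals). Of transcripts described as Cc-nbs-lrr, NbS00002865g0003.1 was 20.4-fold higher (31.1-fold without mock replicate 2), NbS00014857g0016.1 18.1-fold higher and NbS00004466g0001.1 24.9-fold lower (75.4-fold without RSV replicate 1 and 14.6-fold without RSV replicate 3). The Nbs-lrr transcript NbS00050904g0006.1 was 1.79-fold lower. This call was lost by DESeq2 (adjusted p = 0.22), when scaled by library totals (adjusted p = 0.293), without the low-count filter, and without any 1 library except RSV replicate 3. The Ethylene list had a median of 0.28 (camera, adjusted p = 0.000984, and adjusted p = 0.477 with an estimated correlation). The Disease resistance list had a median of 0.36 (camera, adjusted p = 0.00413, and adjusted p = 0.574 with an estimated correlation). It was not called by fry (adjusted p = 0.122), when scaled by library totals (adjusted p = 0.0747) or without RSV replicate 3 (adjusted p = 0.0503, median 0.12). Over its 12 alternatives the adjusted p ran from 4.4e-05 to 0.574.

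The classical defence markers were not called as a list by camera. Of 31 Pathogenesis-related proteins 7 rose and 12 fell (8 and 14 adjusted over the list alone, 12 and 7 when scaled by library totals). Endochitinase (NbS00010078g0005.1), which degrades fungal cell walls, was at 0 in all mock libraries and at least 14.7-fold higher in RSV leaves (at least 10.2-fold without RSV replicate 3). One Thaumatin-like protein (NbS00045440g0005.1) was 8.94-fold higher (3.47-fold without RSV replicate 3, and not called without mock replicates 1, 2 or 3, with adjusted p of 0.071, 0.063 and 0.0504). The Pathogenesis-related protein PR-1 transcript NbS00050413g0001.1, of the family used as a marker of salicylic acid responses, was 5.18-fold lower at 1.63 ± 0.986 against 7.98 ± 0.923 CPM, and another Thaumatin-like protein (NbS00056538g0007.1) was 3.28-fold lower. The list median was -0.19, its mean 0.27 and its median 0.22 when scaled by library totals (camera, adjusted p = 0.4, called by fry at 0.0219, with a range of 0.0219 to 0.855 over the 12 alternatives). Among 60 beta-1 3-glucanases, an added group that the list had missed, 10 rose and 16 fell (19 and 7 when scaled by library totals). In the Salicylic acid signalling list 6 of 17 members rose and 3 fell (7 and 4 adjusted over the list alone, 9 and 3 when scaled by library totals; camera, adjusted p = 0.519).

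The other hormone lists were not called by camera. Their medians, in log2, were -0.02 for Jasmonate (9 rose and 9 fell of 43; adjusted over the list alone also 9 and 9; camera, adjusted p = 0.846), -0.18 for Auxin (16 and 42 of 178, the same adjusted over the list alone; adjusted p = 0.116), -0.06 for Gibberellin (5 and 4 of 26, the same adjusted over the list alone; adjusted p = 0.875) and -0.15 for Cytokinin (10 and 16 of 77, the same adjusted over the list alone; adjusted p = 0.184). By fry Auxin (0.04, with a range of 0.04 to 0.523 over the 12 alternatives) and Cytokinin (0.00695, range 0.00695 to 0.455) were called as lower. All 4 medians were positive when scaled by library totals, where 15 rose and 3 fell for Jasmonate, 52 and 13 for Auxin, 9 and 3 for Gibberellin and 21 and 9 for Cytokinin. Abscisic acid had 34 risen and 34 fallen of 156 members (36 and 40 adjusted over the list alone, 68 and 19 when scaled by library totals), a median of 0.07 and an adjusted p of 0.875 by camera. Brassinosteroid had 3 risen and 0 fallen of 13 (2 and 0 adjusted over the list alone, 8 and 0 with a median of 0.67 when scaled by library totals), a median of 0.26 and an adjusted p of 0.4 by camera.

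More protein turnover transcripts rose than fell. In the Proteasome list, the complex that degrades ubiquitin-tagged proteins, 106 of 196 members rose and none fell (118 rose and 1 fell adjusted over the list alone, 156 and 0 when scaled by library totals), and the summed level was 6933 ± 68.1 against 4619 ± 151 CPM. Proteasome subunit alpha type (NbS00004850g0016.1) was 4.77-fold higher at 151 ± 13.9 against 31.7 ± 2.09 CPM. The 26S protease regulatory subunit 6B homolog NbS00002198g0023.1, with 1 mock count in all, had a ratio of 54.9 (95% exact interval 9.58 to 2195; at least 12.2-fold higher without mock replicate 3). Of 33 members of the Autophagy list, the machinery for bulk degradation in the vacuole, 20 rose and none fell (20 and 0 adjusted over the list alone, 31 and 0 when scaled by library totals), with Autophagy-related protein 8 (NbS00052943g0008.1) 2.75-fold and Autophagy-related protein 3 (NbS00001756g0014.1) 2.33-fold higher. In the ER folding and stress list 18 of 49 members rose and none fell (18 and 0 adjusted over the list alone, 33 and 0 when scaled by library totals). Calreticulin 2 (NbS00010155g0009.1), a chaperone of the endoplasmic reticulum, was 2.95-fold higher (1.95-fold without RSV replicate 3), and Protein disulfide isomerase (NbS00061255g0001.1) 2.75-fold higher, a call lost without mock replicates 1 or 2 (adjusted p of 0.0678 and 0.0598). Medians were 0.56 for the Proteasome (camera, adjusted p = 3.89e-14, and adjusted p = 0.281 with an estimated correlation) and 0.71 for Autophagy (camera, adjusted p = 5.48e-06, and adjusted p = 0.46 with an estimated correlation). ER folding had a median of 0.46 (camera, adjusted p = 0.000984, and adjusted p = 0.523 with an estimated correlation, with 0.0761 by fry and a range of 4.41e-05 to 0.523 over its 12 alternatives).

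Transcripts of other protein machinery were not called as lists by camera. In Heat shock proteins and chaperones 54 of 355 members rose and 69 fell (54 and 69 adjusted over the list alone, 146 and 21 when scaled by library totals), with a median of 0.01 and a mean of -0.02 (camera, adjusted p = 0.846). Among Cytosolic ribosomal proteins 16 of 309 rose and none fell (0 and 0 adjusted over the list alone; median 0.07; 128 and 0 with a median of 0.48 when scaled by library totals; camera, adjusted p = 0.33). This list was called without mock replicate 3 (adjusted p = 0.0314) and without RSV replicate 3 (0.00359, with a range of 0.00359 to 0.914 over the 12 alternatives). Ubiquitin E3 ligases rose in 112 of 521 members and fell in 47 (102 and 43 adjusted over the list alone, 266 and 12 when scaled by library totals; median 0.16; camera, adjusted p = 0.0555). They were called without mock replicate 2 (adjusted p = 0.0321), RSV replicate 1 (0.0376) or RSV replicate 2 (0.0377, with a range of 0.0321 to 0.523 over the 12 alternatives). Receptor-like kinases rose in 94 of 568 members and fell in 185 (97 and 192 adjusted over the list alone), with a median of -0.20 that turned to 0.21 when scaled by library totals, where 178 rose and 91 fell (camera, adjusted p = 0.0543). They were called by fry (0.0115) and with library totals (0.0221, with a range of 0.0115 to 0.549 over the 12 alternatives).

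More transcripts of growth and division fell than rose. In the Histones and DNA replication list 69 of 122 members fell and 5 rose (73 and 10 adjusted over the list alone). Its summed level was 3030 ± 293 CPM in RSV and 3587 ± 288 CPM in mock leaves. With library totals 50 fell and 26 rose, with a median of -0.32. A Histone H2A (NbS00034921g0005.1), a core protein of chromatin, was 3.90-fold lower at 4.64 ± 1.90 against 17.4 ± 3.34 CPM. High mobility group protein (NbS00003549g0016.1), a chromatin protein that carries a linker-histone domain but is not a histone, was 5.43-fold lower (8.28-fold without RSV replicate 2). Another Histone H2A (NbS00030290g0015.1) was 1.59-fold higher, a call lost by DESeq2 (adjusted p = 0.0697) and without mock replicate 1, mock replicate 3 or RSV replicate 3, and Proliferating cell nuclear antigen (NbS00022941g0004.1), the sliding clamp of DNA replication, was also 1.59-fold higher. In the Cyclins and cell division list 76 of 146 members fell and 4 rose (83 and 7 adjusted over the list alone). With library totals 42 fell and 12 rose, with a median of -0.16. A Kinesin (NbS00021892g0015.1) and a Kinesin family protein (NbS00014808g0024.1), motors of which several act in the spindle, were 5.66-fold and 5.29-fold lower. Kinesin light chain-like (NbS00002141g0003.1), whose name does not make it a division protein, was 2.36-fold higher, a call lost without mock replicate 1 (adjusted p = 0.0607). The spindle checkpoint component mad2 (NbS00047104g0001.1) was 1.86-fold higher, a call lost by DESeq2 (adjusted p = 0.281), without the low-count filter and without any 1 library. Medians were -0.74 for histones (camera, adjusted p = 7.24e-10, and adjusted p = 0.497 with an estimated correlation) and -0.57 for cyclins (camera, adjusted p = 1.09e-09, and adjusted p = 0.307 with an estimated correlation).

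With TMM factors more cell wall and phenylpropanoid transcripts fell than rose, and more glutathione transferases rose than fell. In the Cell wall list 109 of 228 members fell and 19 rose (126 and 25 adjusted over the list alone). Scaled by library totals 59 fell and 40 rose, with a median of -0.23. Polygalacturonase 2 (NbS00038601g0006.1) and a Polygalacturonase (NbS00015644g0026.1), pectin-degrading enzymes, were 5.64-fold (35.3 ± 20.2 against 197 ± 26.3 CPM) and 5.40-fold lower. An Expansin-like protein (NbS00059116g0015.1), of a family that loosens walls, and a Pectinesterase (NbS00007015g0012.1) were 5.06-fold and 4.13-fold higher. In the Phenylpropanoid and lignin list 41 of 101 members fell and 10 rose (45 and 10 adjusted over the list alone). With library totals 16 fell and 14 rose, with a median of -0.05. Laccase-22 (NbS00033024g0001.1), of a family that polymerises lignin, was 3.41-fold lower and Chalcone--flavonone isomerase (NbS00002235g0012.1), an enzyme of flavonoid synthesis, 2.75-fold lower. Laccase 1a (NbS00005980g0002.1), with 3 mock counts in all, had a ratio of 45.2 (95% exact interval 15.2 to 221; 21.8 without RSV replicate 3 and 94.0 without mock replicate 3). A Cinnamyl alcohol dehydrogenase-like protein (NbS00019196g0005.1) was 24.8-fold higher (12.03-fold without RSV replicate 3). Of 49 Glutathione transferases, enzymes of detoxification, 24 rose and 11 fell (28 and 13 adjusted over the list alone, 29 and 8 when scaled by library totals). Their summed level was 1320 ± 185 CPM in RSV and 1140 ± 50.9 CPM in mock leaves. Glutathione S-transferase NbS00002272g0007.1 was 114-fold higher at 49.1 ± 20.1 against 0.397 ± 0.349 CPM (171-fold without mock replicate 2). The Glutathione S-transferase-like NbS00029167g0003.1, at 0 in all mock libraries, was at least 22.7-fold higher (at least 12.7-fold without RSV replicate 3). The domain protein NbS00032876g0004.1 was 3.88-fold lower and Maleylacetoacetate isomerase (NbS00026241g0004.1), an enzyme of tyrosine breakdown, 2.22-fold lower. Medians were -0.65 for the Cell wall (camera, adjusted p = 1.36e-08, and adjusted p = 0.345 with an estimated correlation), -0.46 for Phenylpropanoid (camera, adjusted p = 0.000452, and adjusted p = 0.307 with an estimated correlation) and 0.73 for Glutathione transferases (camera, adjusted p = 0.0115, and adjusted p = 0.523 with an estimated correlation, with 0.0787 by fry and a range of 0.000497 to 0.523 over the 12 alternatives).

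**Figure D2:**
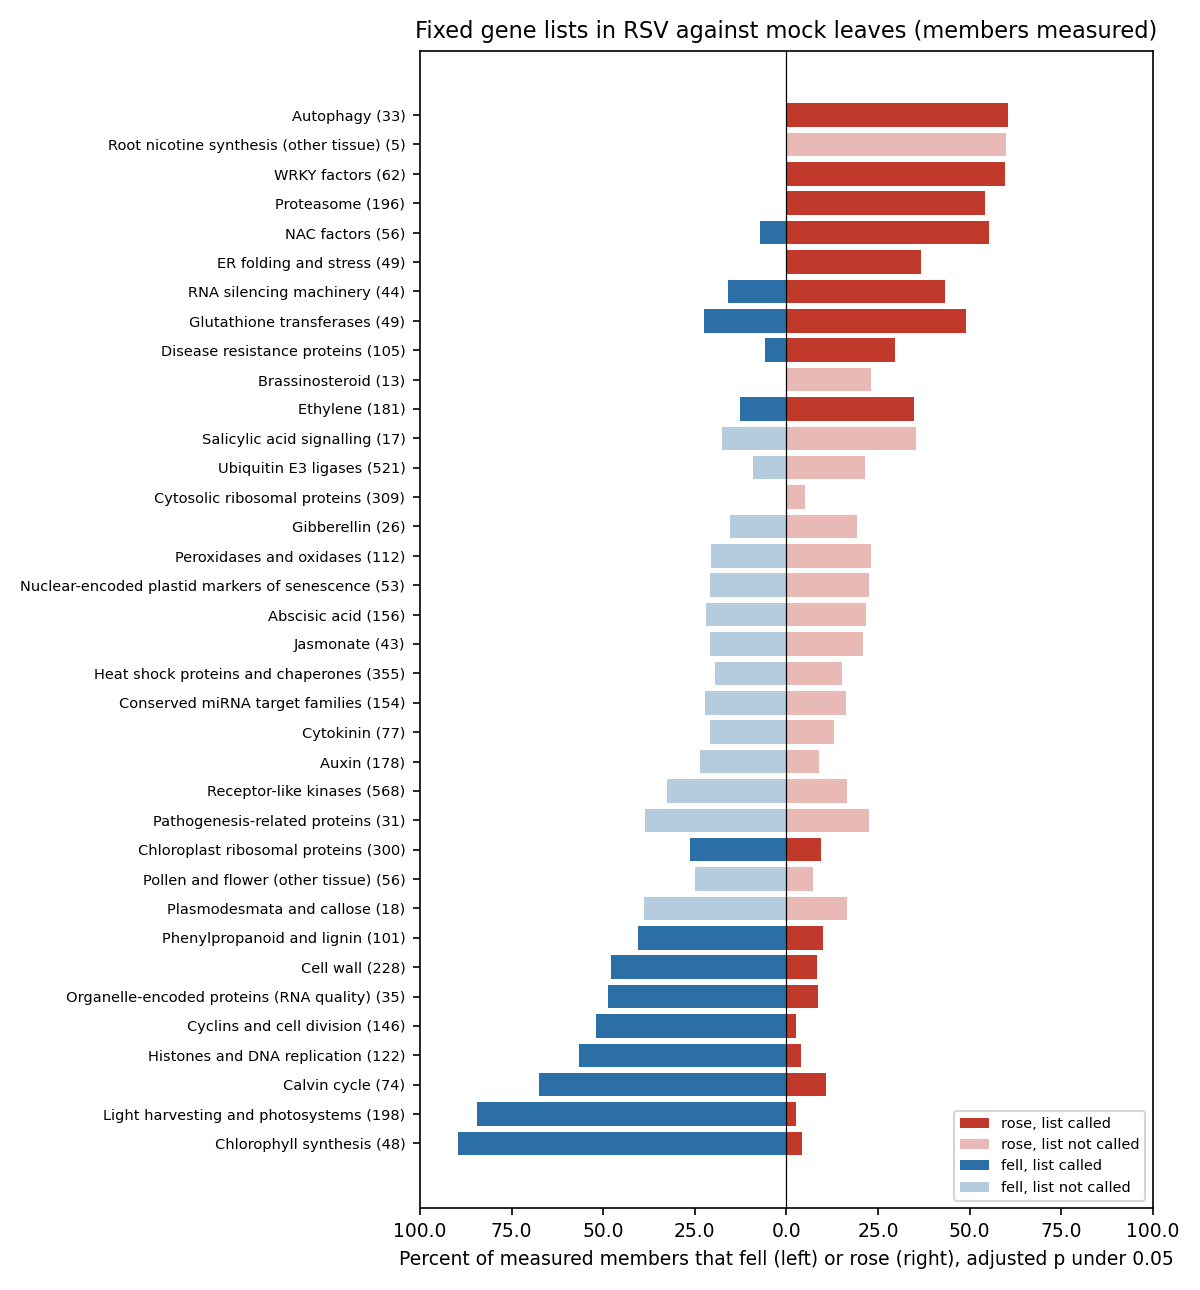
Percent of the measured members of each of the 36 tested gene lists that fell (left, blue) or rose (right, red) in RSV against mock leaves. The number of measured members is in brackets, and the lists are ordered by the percent that rose minus the percent that fell. Dark bars mark the 18 lists called by camera and pale bars the others. Chlorophyll synthesis, light harvesting and the Calvin cycle have the largest shares of members that fell, and no WRKY, autophagy or proteasome member fell; scaled by library totals the chloroplast ribosomal list and 8 of the pale lists have medians of the other sign.

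With an estimated inter-gene correlation none of the 18 lists was called, with adjusted p of 0.281 to 0.773. For each of the 18 lists this was the highest of the 12 alternatives. The estimated correlation of the RNA silencing list was 0.0079, below the preset 0.01, yet its adjusted p by camera went from 0.00259 to 0.307. A larger correlation therefore did not end the call of that list. In the other called lists the estimate ran from 0.0331 to 0.557. Peroxidases and oxidases had 26 risen and 23 fallen of 112 members (27 and 26 adjusted over the list alone; camera, adjusted p = 0.825), and Plasmodesmata and callose 3 and 7 of 18 (3 and 8 adjusted over the list alone; camera, adjusted p = 0.0635). The latter was called by fry (0.0115), with library totals (0.0487) and without mock replicate 3 (0.0451), with a range of 0.0115 to 0.345 over the 12 alternatives. The senescence markers had 12 and 11 of 53 (13 and 13 adjusted over the list alone; camera, adjusted p = 0.336, called by fry at 0.0191, range 0.0191 to 0.552). The Conserved miRNA target families had 25 risen and 34 fallen of 154 members (the same adjusted over the list alone), with a median of -0.19 that turned to 0.23 when scaled by library totals, where 46 rose and 18 fell (camera, adjusted p = 0.364, called by fry at 0.0208, range 0.0208 to 0.523). Among the markers of other tissues, Root nicotine synthesis had 3 risen and 0 fallen of 5 (the same adjusted over the list alone, 5 and 0 when scaled by library totals; camera, adjusted p = 0.102). It was called without the low-count filter (0.0351) and without RSV replicate 2 (0.0406), with a range of 0.0351 to 0.552. Pollen and flower had 4 and 14 of 56 (the same adjusted over the list alone), with a median of -0.25 that turned to 0.16 when scaled by library totals, where 17 rose and 7 fell (camera, adjusted p = 0.166, called by fry at 0.00532, range 0.00532 to 0.345). With library totals the counts were 45 risen and 10 fallen for Peroxidases, 5 and 4 for Plasmodesmata and 26 and 1 for the senescence markers. The lists for Sesquiterpenoid phytoalexins and Trichome had 1 measured member each and were not tested: the first rose from 2.63 ± 0.394 to 13.7 ± 6.04 CPM, and the second was at 1.98 ± 1.04 against 1.48 ± 1.23 CPM.

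The largest rises included transcripts nearly silent in mock leaves. Phosphoglycerate mutase family protein (NbS00004569g0028.1), whose family includes a glycolytic enzyme, and GDSL esterase/lipase At1g28600 (NbS00015946g0003.1), at 0 in all mock libraries, were at least 61.2-fold (at least 23.1-fold without RSV replicate 3) and at least 49.6-fold higher. Beta-1 3-glucanase (NbC25742659g0003.1), which degrades callose and fungal glucan, had a ratio of 386 on 1 mock count (95% exact interval 68.9 to 15260; 93.9 without RSV replicate 3, and at least 72.7-fold higher without mock replicate 1). The ratio was 156 for PAR-1c protein (NbS00042659g0005.1) on 1 mock count (27.7 to 6184; 45.2 without RSV replicate 3, and at least 27.3-fold higher without mock replicate 2). For Ethylene-responsive transcription factor 13 (NbS00023305g0001.1) it was 116 on 3 mock counts (39.4 to 564; 241 without mock replicate 3). A transcript described only as Genomic DNA chromosome 3 TAC clone K1G2 (NbS00000158g0003.1) was 189-fold higher at 82.3 ± 13.5 against 0.410 ± 0.141 CPM. A 60s acidic ribosomal protein P1 (NbS00008747g0007.1), from the ribosomal stalk, was 172-fold higher at 74.7 ± 12.6 against 0.410 ± 0.141 CPM, and an AAA-ATPase (NbS00054564g0002.1) 110-fold higher at 65.3 ± 23.5 against 0.556 ± 0.309 CPM. Among added groups, 27 of 58 GDSL esterases fell and 8 rose (13 and 10 when scaled by library totals). Of 6 transcripts described as 60s acidic ribosomal protein P1, 2 rose and 0 fell. The 1-aminocyclopropane-1-carboxylate oxidase and the Glutathione S-transferase NbS00002272g0007.1 given above complete the 10 largest rises. The adjusted p of these 10 lay between 2.987e-06 and 0.009828 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

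The largest falls were smaller. A Tumor-related protein (NbS00010762g0004.1) was 38.0-fold lower, at 3.95 ± 3.00 against 140 ± 105 CPM (57.5-fold without RSV replicate 1 and 25.1-fold without RSV replicate 3). An F-box transcript (NbS00007888g0007.1), of a family that picks proteins for ubiquitin tagging, was 33.4-fold lower (21.6-fold without mock replicate 1 and 68.6-fold without RSV replicate 1). UDP-glucosyltransferase family 1 protein (NbS00055327g0003.1), of a family that attaches sugar to small molecules, was 14.8-fold lower at 4.33 ± 0.695 against 64.7 ± 23.4 CPM. The others were a transcript described by a sorghum organelle-targeted protein (NbS00004698g0002.1, 14.1-fold, and 33.2-fold without RSV replicate 1), Os03g0133300 protein (NbS00041766g0008.1, 12.5-fold), Gibberellin-regulated protein 2 (NbS00019582g0004.1, 9.79-fold, and 6.24-fold without RSV replicate 3), and a BHLH transcription factor (NbS00026711g0011.1, 9.48-fold). They also included RAG1-activating protein 1 homolog (NbS00000996g0003.1, 9.39-fold), of the SWEET sugar transporter family, Cortical cell-delineating protein (NbS00019865g0002.1, 9.09-fold) and a CHY zinc finger protein (NbS00015751g0019.1, 9.04-fold), all lower in RSV leaves. The adjusted p of these 10 lay between 8.373e-05 and 0.005912 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

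The small RNA comparison asks which RSV-derived small RNAs, the products of silencing of the viral RNA, accumulated in infected leaves. RSV-derived small RNAs of 19 to 24 nt made up 31639.6 ± 9189 RPM (mean ± SD, n = 3), or 3.16% of all small RNA reads, in RSV leaves, with 41355 RPM, 30475 RPM and 23089 RPM in replicates 1 to 3. The mock libraries listed 4.55 RPM (56 reads), 118 RPM (1428 reads) and 3886 RPM (40537 reads) in replicates 1 to 3. The lowest RSV library lay 5.94-fold above the highest mock library, which was mock replicate 3. On the log2(RPM + 1) scale the groups differed by 7.81 (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 allows), by 5.50 without mock replicate 1 and by 10.23 without mock replicate 3.

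The reads listed for mock replicate 3 fell on 406 sequences, counted per segment. RSV replicate 3 was at 0 in the 406 lines that list these reads, and 44 of the sequences had RSV replicate 3 reads in a second line. RSV replicate 3 was also at 0 in the 1174 lines that list reads in mock replicate 2. An alternative added after seeing the data read the lines that list reads in mock replicate 2 or 3 one column further right. The recovered reads were moved and then scaled by the total of the library they moved to. In this version the mock libraries hold 3.09 RPM, 1.49 RPM and 137 RPM, the RSV libraries 33141.7 ± 9436 RPM, and the difference is 11.49. There the lowest RSV library lies 184-fold above the highest mock library, RNA1 holds 87.4% of the RSV-library reads and the 20 nt class 39.2%. The values below were taken from the columns as deposited.

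RNA1, the segment that codes for the viral polymerase, gave 86.8 ± 3.62% of the RSV-derived reads (mean ± SD, n = 3 RSV libraries), RNA4 gave 8.38 ± 2.03%, RNA3 3.32 ± 1.06% and RNA2 1.498 ± 0.530%. Counted as distinct sequences, RNA1 gave 68.6%. These shares are not per kilobase, since segment lengths were not used here. In mock replicate 2 RNA1 held 76.0% of 1428 reads.

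The 20 nt class was about as large as the 21 nt class. Of the RSV-derived reads, 39.3 ± 5.19% were 20 nt and 38.4 ± 2.16% were 21 nt long, followed by 18.6 ± 2.71% of 22 nt, 1.81 ± 0.276% of 19 nt, 1.37 ± 0.423% of 23 nt and 0.552 ± 0.248% of 24 nt (n = 3 RSV libraries). The 20 and 21 nt means differed by less than the SD of the 20 nt class. The 21 and 22 nt classes, the main products of the plant Dicer-like enzymes 4 and 2, summed to 57.0 ± 4.82%. They held 50.1% (95% exact interval 47.5 to 52.8) in mock replicate 2 and 59.6% (59.1 to 60.1) in mock replicate 3, the mock libraries with at least 100 reads (exact two-sided permutation test, p = 0.6, where the smallest possible p is 0.2). With the lines moved, only mock replicate 3 holds at least 100 reads, which are the 1428 listed for mock replicate 2, and no comparison of groups was made.

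Reads starting with U made up 38.1 ± 1.70% and with A 31.8 ± 0.728% of the RSV-derived reads, together 69.9 ± 1.54%, against 17.8 ± 0.708% for C and 12.2 ± 1.14% for G (n = 3). At all other positions of the reads U made up 28.1 ± 0.608%, A 30.5 ± 0.424%, C 19.6 ± 0.600% and G 21.8 ± 0.548%. The first base was thus richer in U and poorer in G than the rest of the read by more than the spread between libraries. Counted as distinct sequences, A and U together made up 65.3%. The first base is the one by which Argonaute proteins sort small RNAs.

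The 5 sequences with the highest mean over the RSV libraries all came from RNA1, and each was lowest in RSV replicate 3. The 10 highest held 4.61%, 3.92% and 1.44% of the RSV-derived reads in RSV replicates 1 to 3, so replicates 1 and 2 weighed most in the order. AACTGAGACTGACAAGAGCTT (21 nt) had 297 RPM, 169 RPM and 44.8 RPM in RSV replicates 1 to 3, TGGCACTAAGTTTCTGGGAAC (21 nt) 191 RPM, 176 RPM and 25.5 RPM, TATGATTATGCACCCAGAAC (20 nt) 130.5 RPM, 198 RPM and 23.4 RPM, AATTGAACACTGATGATAAGG (21 nt) 169 RPM, 157 RPM and 24.7 RPM, and TGGATGCAAAGAATATTGTTC (21 nt) 257 RPM, 43.2 RPM and 36.4 RPM. In the mock libraries these sequences were at 0, except 0.248 RPM of the fourth in mock replicate 2. Of 517 sequences with a mean of at least 10 RPM in one group, 467 were higher in RSV leaves and 0 were lower (limma on log2(RPM + 1), Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05 the counts were also 467 and 0, and the added tests on recovered reads gave 474 and 0 with edgeR and 472 and 0 with DESeq2. With the lines moved one column right, 544 of 547 sequences were higher and 0 lower by limma, and 547 and 0 by edgeR. The table lists RSV-derived sequences only, which were rare in the mock libraries except mock replicate 3. Most sequences could therefore pass the minimum only through the RSV group, so the direction was largely set in advance in all these tests.

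**Figure D3:**
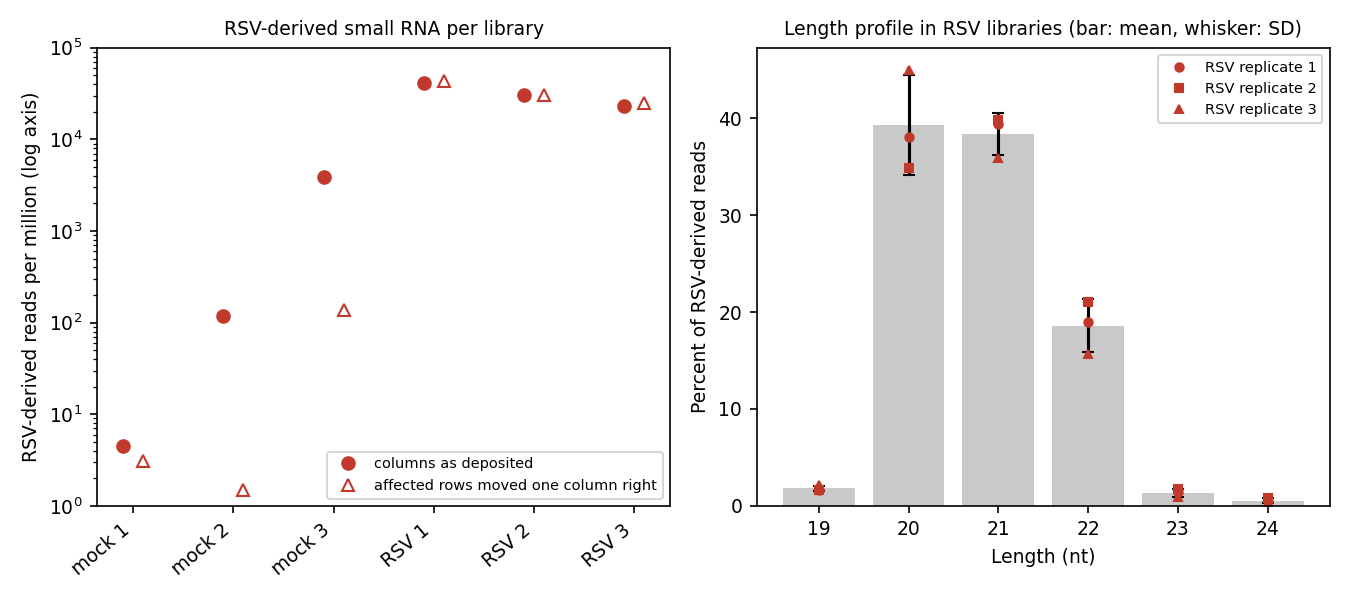
Left, RSV-derived small RNA per library in RPM on a log axis, as deposited (filled circles) and with the affected lines moved one column to the right (open triangles); right, the percent of RSV-derived reads of each length in the RSV libraries, with bars for the mean of 3 libraries, whiskers for the SD and points for each replicate. Mock replicate 3 stands at 3886 RPM as deposited and at 137 RPM after the move, and the 20 nt and 21 nt classes hold 39.3% and 38.4% of the reads.

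The degradome asks which host transcripts were cleaved at defined positions in RSV leaves. Growth-regulating factors, transcription factors of leaf growth that a conserved plant miRNA family cleaves, held the peak with the most tags among the miRNA target families: 6 of 18 transcripts with tags had a peak of at least 10 tags, and in all 6 it held at least 20% of the tags of the transcript. Growth-regulating factor 5 (NbS00059094g0005.1) had 119 of its 129 tags (92.2%, 95% exact interval 86.2 to 96.2) at position 413. Growth-regulating factor 4 had 116 tags at position 278 (NbS00049354g0008.1, 73.4%, 65.8 to 80.1) and 116 at position 412 (NbS00058989g0004.1, 72.5%, 64.9 to 79.3). Another Growth-regulating factor 5 had 107 at position 341 (NbS00030819g0006.1, 74.3%, 66.4 to 81.2), and Growth-regulating factor 3 had 98 at position 578 (NbS00054622g0003.1, 95.1%, 89.0 to 98.4). None of these tags had a single mapping place, so they cannot be assigned to one of these copies. Of the 5, the mRNA of NbS00049354g0008.1 rose in RSV leaves by 1.02 on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.01922), NbS00058989g0004.1 differed by 0.57 without passing it (adjusted p = 0.1713), and 3 were too low to be tested.

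**Figure D4:**
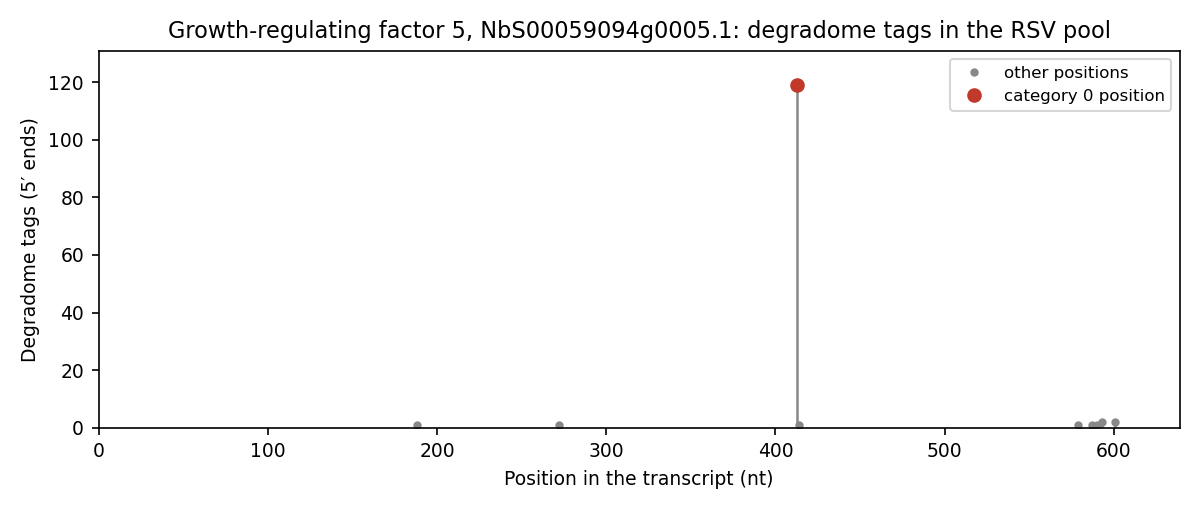
Degradome tags by the position of their 5′ end (nt) in the transcript of Growth-regulating factor 5, NbS00059094g0005.1, in the pooled RSV library; the red point is the category 0 position and grey points are the other positions. The 119 tags at position 413 stand above at most 2 tags at any other position.

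The peaks of the other families held at most 84 tags. Auxin response factors had a peak in 11 of 60 transcripts (9 with at least 20% of the tags), SQUAMOSA promoter-binding proteins in 6 of 39 (2), AP2-like factors in 7 of 31 (3), laccases in 7 of 45 (4), Nuclear transcription factor Y subunits in 2 of 16 (2), ARGONAUTE 1 in 7 of 17 (1) and homeobox-leucine zipper proteins in 0 of 17. Together 46 of 243 transcripts of the Conserved miRNA target families had a peak (18.9%), against 13.8% of 49045 others (Fisher's exact test, odds ratio 1.45, p = 0.0254, and adjusted p = 0.0609 over the 36 lists). Of 10000 random lists matched on total tags none reached 46 (median 21, central 95% from 15 to 28). Where the peak had to hold at least 20% of the tags of its transcript, 27 of 243 (11.1%) had one against 1.58% of the others (Fisher's exact test, odds ratio 7.81, p = 6.06e-15). Growth-regulating factors gave 6 of these 27. Tags were placed at every location they fitted, so 1 pile can count as a peak in several near-identical copies. The Fisher tests and random lists treat such copies as independent. The 5 named growth-regulating factor peaks held 98 to 119 tags, but 16.7 to 22.7 when weighted by mapping places. With tags of 1 mapping place alone, 6 of 243 had a peak (Fisher's exact test, odds ratio 0.746, p = 0.590), where 10000 matched random lists had a median of 5 (1 to 10) and 62.4% of them lay below 6. At a minimum of 5 or 50 tags the odds ratios were 1.07 (p = 0.619) and 1.62 (p = 0.192, both Fisher's exact test). Matched random lists had a median of 58 (48 to 68) at 5 tags, where 99.7% of them lay below the 73 of the families, and of 3 (1 to 6) at 50 tags, where 99.9% lay below their 9.

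Across the library, 6832 of 49288 transcripts (13.9%) had a peak of at least 10 tags, with a median of 18 tags and 6.01% of the tags of the transcript. The described transcripts with the most tags at 1 position were Os03g0111400 protein (NbS00023394g0001.1, which carries a heavy metal transport domain, 12479 tags at position 79, 91.3%, 95% exact interval 90.9 to 91.8) and 50S ribosomal protein L23 (NbS00006831g0015.1, 3302 at position 155, 98.5%, 98.04 to 98.9). Next came T-complex protein eta subunit, part of a cytosolic chaperonin (NbS00039197g0009.1, 1588 at position 993, 78.1%, 76.2 to 79.9, and NbS00057302g0013.1, 1583 at position 906, 77.7%, 75.8 to 79.5), and Fasciclin-like arabinogalactan protein 9 (NbS00027714g0004.1, 1254 at position 444, 46.9%, 45.04 to 48.9). Only the tags of Os03g0111400 protein had a single mapping place, apart from 5 tags of NbS00039197g0009.1 and 9 of NbS00027714g0004.1. The mRNA of none of these 5 was called, with log2 changes of 0.12, -0.34, 0.27, 0.31 and -0.64 in the same order.

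Peaks were commonest in highly expressed groups: 66.7% of 333 Cytosolic ribosomal proteins, 56.2% of 274 Light harvesting transcripts and 53.0% of 83 Calvin cycle transcripts had one, against 2.03% of 295 Disease resistance transcripts (Fisher's exact test, adjusted p over 36 lists of 2.80e-107, 1.34e-59, 3.59e-16 and 1.27e-11). In 5 equal bins of rising mean mRNA level the share with a peak was 6.17%, 9.85%, 14.4%, 23.7% and 50.4%. Among 29997 transcripts with mRNA values and tags, 21.8% of the 6273 with a peak fell in RSV leaves against 16.99% of the others (odds ratio 1.36, p = 5.55e-18, Fisher's exact test), and 20.9% against 17.3% rose (odds ratio 1.26, p = 1.66e-10, Fisher's exact test). Among transcripts with a mean level above the median, 25.1% of those with a peak fell against 22.7% of the others (odds ratio 1.14, p = 0.00110), and 21.8% against 19.1% rose (odds ratio 1.18, p = 9.91e-05, both Fisher's exact test). For peaks of at least 5 tags the odds ratios were 1.16 for falls (p = 8.03e-07) and 1.32 for rises (p = 1.17e-19, both Fisher's exact test). For peaks of at least 50 tags the odds ratios were 1.90 for falls (p = 6.27e-19) and 0.822 for rises (p = 0.0214, both Fisher's exact test). Transcripts are not replicates, so these p-values describe this library.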

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

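Scaling by library totals, the move of small RNA reads by a column, the count tests on recovered reads and the tags with 1 mapping place were chosen only after results were seen. Of the values of the 82 named transcripts under the alternatives, 910 kept their direction and their side of the threshold, 39 values of 9 transcripts kept the direction and lost the call, and 0 reversed. These transcripts were picked from the same data as called and with groups that did not overlap. That choice favours this outcome, so it does not describe called transcripts in general. For the 36 tested lists, 386 values kept their side of the threshold, 27 lost the call and 19 gained one. The number of changed transcripts was 6163 at an adjusted p under 0.01, a stricter threshold, and 2938 rather than 5319 changed by at least 2-fold where at least 10 CPM in 3 libraries was required, which tests fewer transcripts. DESeq2 called 7797 transcripts, 4825 of them by at least 2-fold. With an estimated correlation camera called 0 lists, and fry called 22. For the RNA silencing list the estimate of 0.0079 lay below the preset 0.01, so a larger correlation did not end its call. The cause was not tested further. Counted as distinct sequences, the share of 5′ A and U was 65.3% and that of RNA1 68.6%; this weighting gives a rare sequence the weight of an abundant one. Of sequences with a mean of at least 100 RPM, 7 of 8 were higher in RSV leaves, and of those with at least 2 RPM, 2460 of 2683, because the minimum sets how many are tested. Transcripts with a degradome peak numbered 28445 at 2 tags, 14092 at 5 tags and 1146 at 50 tags, as the minimum sets. They numbered 800 where the peak also held at least 20% of the tags. With tags of 1 mapping place, where fewer tags are counted, they numbered 1616. The odds ratio of the miRNA target families was 1.07 at 5 tags, 1.62 at 50 tags and 0.746, the reverse direction, with tags of 1 mapping place; the cause was not tested.

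Leaving out 1 library at a time gave 7995 to 10290 changed transcripts, 4338 to 6231 changed by at least 2-fold, 17 to 20 called lists and 317 to 541 changed small RNA sequences. The log2 difference of small RNA totals ran from 5.50 (without mock replicate 1) to 10.23 (without mock replicate 3). The share of 21 and 22 nt ran from 55.0% to 59.6%, that of RNA1 from 85.1% to 88.7% and that of 5′ A and U from 69.4% to 70.8%. The strand share could not be run, since the table gives no strand. Where a group was left with 2 libraries, the tests pooled the spread of all libraries.

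With the replicate number as a block, 9549 transcripts changed, 5186 of them by at least 2-fold, 18 lists were called and 470 of 517 small RNA sequences changed. The block ended the calls of the Chloroplast ribosomal list (camera, adjusted p = 0.0711, median 0.02) and of mad2 (NbS00047104g0001.1, log2 0.88, adjusted p = 0.0711, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and gave a call to Ubiquitin E3 ligases (camera, adjusted p = 0.0496). The numbers did not pair the libraries: the deviations of same-numbered libraries correlated by 0.15, -0.14 and -0.15 for mRNA and by -0.39, -0.55 and -0.71 for small RNA. At this depth, replicate number and spread edgeR recovered 56% of simulated 2-fold changes, and which of these limits it was not tested. Far fewer transcripts were changed in the simulation than were called here, so the share recovered in the real data can differ. Mock replicate 1 held too few RSV-derived reads (56) for a length profile.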

Other observations

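The 2 tests of the mock replicate 3 reads, the scaling test of the light harvesting list, and the groups of transcripts below that the lists had not fixed, were chosen only after the values were seen. Families of transcripts with the same description, outside the fixed lists, also changed together. Of 581 families with enough members, 54 outside the lists passed (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05), where the members of a family are not independent. Aquaporins, the water channels of plant membranes, fell in 25 of 32 transcripts and rose in 2 (adjusted p = 8.87e-11, Fisher's exact test), and 18 fell and 4 rose when scaled by library totals. By description text, 49 of 60 aquaporin transcripts fell and 2 rose (38 and 7 when scaled by library totals), with a sum of 4809 ± 885 CPM in RSV and 11901 ± 1292 CPM in mock leaves (mean ± SD, n = 3 each). Endoglucanase 1, of a family that acts on cell wall glucans, fell in 14 of 14 transcripts (adjusted p = 1.14e-08, Fisher's exact test), and Major latex-like protein in 11 of 12 (adjusted p = 6.49e-06, Fisher's exact test). Carbonic anhydrase, which interconverts CO2 and bicarbonate, fell in 6 of 10 transcripts, from a sum of 2231 ± 101 to 427 ± 138 CPM, and when scaled by library totals 3 fell and 1 rose. Phosphoenolpyruvate carboxylase 1 fell in 9 of 9 transcripts (adjusted p = 1.4e-05, Fisher's exact test), and in 1 when scaled by library totals.

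Among rising families, Ribonuclease 3-like protein 3, of the RNase III family that also includes Dicer, rose in 9 of 14 transcripts with a median log2 change of 2.58 (adjusted p = 0.00317, Fisher's exact test), and 4 of the 14 stand in a fixed list. Prohibitin 1-like protein, of a mitochondrial membrane scaffold, rose in 8 of 8 transcripts with a median of 1.77, and Nucleolar GTP-binding protein, a ribosome assembly factor, in 8 of 8 with a median of 0.82 (adjusted p = 4.56e-05 for both, Fisher's exact test). Elongation factor 1-beta, of protein synthesis, rose in 9 of 9 (adjusted p = 1.4e-05, Fisher's exact test), and NADH dehydrogenase, of respiration, rose in 13 of 22 and fell in 2 (adjusted p = 0.000627, Fisher's exact test).

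The light harvesting list fell in RSV leaves, with 110893.7 CPM, 121603.7 CPM and 86485.2 CPM in RSV replicates 1 to 3 and 211017 CPM to 220411 CPM in the mock libraries. Scaled by library totals its own median was -0.64, with 145 fallen and 7 risen, which argues against the choice of TMM factors over library totals as the source. Its summed level differed by -1.02, which argues against reads moved between near-identical copies, and the median without RSV replicate 3 was -0.89, which argues against 1 library alone. A response of the leaf to RSV, a difference in leaf state and a difference in RNA quality stay open and were not tested.

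The reads that mock replicate 3 listed fell on 406 sequences, where a draw of as many reads from the RSV libraries gave 12345 to 12690. Of 113 of these sequences with at least 20 reads in RSV replicates 1 and 2, RSV replicate 3 was at 0 in 98.2%, against 3.67% of 1171 sequences with no mock reads, which argues against carry-over or infection of the mock plant. Values standing one column to the left in 276 lines with reads in mock replicates 2 and 3 and RSV replicates 1 and 2 are consistent with the column ratios, of 2.02 and 1.06 against 2.06 and 0.904 elsewhere, which differed by at most 0.23 (log2). In mock replicate 3 all values lay within 0.01 of a whole multiple of 0.0959 RPM. A read of RSV replicate 1 was worth 0.109 RPM. This argues against a move of the scaled values, so a move would have come before the scaling. Whether reads were moved was not tested further. After the move mock replicate 3 held 137 RPM, so it would still stand above the other mock libraries.

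The 20 nt class held 39.3% of the RSV-derived reads, and 39.3% without the 10 most abundant sequences, which argues against a few sequences as its source. Among pairs of 20 nt reads on opposite strands, overlaps of 19 nt were 1.12 times as frequent as those of 18 nt (1.05 to 1.19 in single RSV libraries), and those of 17 nt 0.976 times (0.915 to 0.997). The first is consistent with 20 nt reads that are 21 nt products short of their last base, and loss of the first base stays open, as its gap from 1 lies within the spread between libraries. The same ratio was 0.992 for 21 nt reads and 0.759 for 22 nt reads. Whether bases were lost in the plant or in the library stays open. Duplexes of 20 nt would overlap by 18 nt. In the RSV libraries together, 18 nt overlaps came to 34934 pairs weighted by reads, against 34088 at 17 nt and 39179 at 19 nt. The 18 nt overlap thus did not stand out, and a Dicer product of 20 nt also stays open.

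The 6 mRNA libraries have 10 splits into 3 and 3, too few for a share under 0.05. For changed transcripts 1 of 10 splits, the real one, gave as many. The real value was 10991 and the highest other 0, and for changes of at least 2-fold 5319 and 0, with 1 of 10. Every other split mixes RSV and mock libraries, so a difference between RSV and mock enters the spread within its groups. The 0 calls there therefore decide nothing. For called lists 3 of 10 splits gave as many, with 18 in the real split and 20 as the highest other. The lowest other gave 6, so camera with the preset correlation also called lists in mixed splits. For changed small RNA sequences 1 of 10 splits gave as many, with 467 and 0. The 517 sequences tested in each split had been chosen with the real groups.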
